A study of Mus musculus with 4 samples.

How the data were processed

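Immune cells were profiled by single-cell RNA sequencing from subcutaneous MC38 tumours (a mouse colorectal tumour line) of WT mice and of mice with a conditional knockout (cKO) of Trim25, which the series title places in T cells. There were 4 libraries, 2 per genotype, named WT-1, WT-2, cKO-1 and cKO-2. Per the labels' protocols, CD45-positive cells were sorted by flow cytometry and libraries were made with a Chromium 3' kit of the v3 chemistry. The deposited files hold whole-number UMI counts per gene and cell barcode, not normalized, 1 matrix per library. Cell Ranger, STAR and the mouse build mm10 are named in the submitters' processing notes; their versions, the annotation and the cell-calling settings are not given in the sources used here. Every deposited barcode held at least 500 UMIs, and whether empty droplets remain among them was not tested. Feature identifiers were matched by gene ID to GENCODE vM21 on GRCm38, the build also called mm10, and 32158 of 32285 matched. Nothing in the labels says that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. The libraries were compared in pairs by a chi-square test of their counts: chi-square per degree of freedom was 69.2 between the WT libraries and 53.5 between the cKO libraries, and 44.0 to 102.2 between genotypes, so no library was a repeat of another.

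Depth was 96751399 UMIs in 10385 barcodes for WT-1, 127449324 in 12318 for WT-2, 101176581 in 8533 for cKO-1 and 115111783 in 9654 for cKO-2. Cells with at least 300 genes, at least 500 UMIs and at most 15% mitochondrial UMIs were kept, which left 10222, 12092, 8205 and 9387 cells. Doublets were scored per library with Scrublet as implemented in scanpy. Its automatic threshold marked 0, 1, 0 and 0 cells and so had not worked. Cells with a score above 0.2 and clusters with a median score above 0.1 were therefore set apart as mixed droplets, a rule chosen after the scores were seen. Scores above 0.2 were found in 1.86% of WT-1, 1.61% of WT-2, 0.987% of cKO-1 and 1.64% of cKO-2 cells.

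Clustering used python 3.11.15 with scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and pandas 2.3.3, on log-normalized counts of 2000 variable genes, 30 principal components and 15 neighbours, with Leiden resolution 1. Trim25, Vsir and Cd4 were left out of the clustering genes. T and NK clusters were taken out and clustered again alone. A cluster was named from marker genes of 20 classes, fixed before the data were examined together with the designs, gene lists and naming rule. Class names below stand for clusters that resemble that class by these markers, so "macrophages" means macrophage-like cells. A cluster with a low median UMI count and none of its class's markers among its leading genes stayed unnamed.

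Raw counts were summed per library and class, and cells were never treated as replicates. The CD8 T, CD4 conventional T and Treg classes were also summed together, and "all T cells" below means this pool. It leaves out gamma-delta T cells and the T or NK cells without a class name. Each class with at least 20 cells in every library was tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, a quasi-likelihood F test of cKO against WT over the 4 libraries of that class, and Benjamini-Hochberg adjustment over all genes tested in the class, with a threshold of 0.05. All p-values are two-sided, and "adjusted p" without another tool's name is from this edgeR test. Numbers of cells per class, and per T and NK cluster, were tested with the same edgeR model with the log of the library's cells as offset. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333. Differences of the genotype effect between classes were tested as an interaction in edgeR with the library as a term. Levels are CPM (counts per 1e+06 counts of a class sum), as mean ± SD of 2 libraries, and fold changes are log2 of cKO over WT ± SE. Where a gene had no count in a group, the fold is a bound against a floor of 3 counts over the group, which covers counting error only.

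There were 19 fixed gene lists. Lymphoid classes were tested for cytotoxic and effector molecules; inhibitory receptors and exhaustion; naive, memory and stem-like T cell genes; T cell receptor signalling and activation; Treg function; and lymphocyte trafficking. Myeloid classes were tested for other checkpoint ligands, inflammatory macrophage genes, tissue-repair and suppressive macrophage genes, lipid and phagocytic macrophage genes, and monocyte and neutrophil chemoattractants. All 6 main classes were tested for the type I interferon response, the interferon gamma response with antigen presentation, proliferation, glycolysis with hypoxia, oxidative phosphorylation, the unfolded protein response, immediate early with dissociation stress genes, and VISTA with its reported partners. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of a class. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's genes move on balance one way and does not compare them with other genes. Members not found, duplicated in the annotation or under the filter were not counted.

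The genes named were, per main class, Trim25 and Vsir, up to 10 that rose and 10 that fell with the largest fold change among those past the threshold with a mean of at least 20 CPM and no overlap between genotypes, and up to 4 members of each list with the smallest p. Fewer were named where the text would repeat itself. Gene models named Gm or Rik, variable segments, mitochondrial and sex-linked genes were counted but not named by size. Genes named outside this rule are said to be so. The result of 1 gene that the rule named is not reported here.

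Alternatives were DESeq2 1.42.0 size factors in the edgeR fit, the DESeq2 Wald test, no filter on low counts, each library left out in turn, the replicate number as a block, stricter cells (at least 500 genes, at most 10% mitochondrial UMIs), predicted doublets kept, Leiden resolution 2 (or 0.5 for T and NK clusters), sums thinned to the smallest library, TMM factors or another denominator for shares, an estimated correlation and fry for lists. Fits of single clusters, a denominator of named immune cells, T and NK clusters at resolution 2, a crossed pairing and the comparisons with plasmacytoid dendritic cells and the fibroblast-like class were chosen after seeing the data. Neither the reads nor cell annotations of the authors were used here.

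The tests of genes, interactions, gene lists and shares were run on simulated data drawn from the real means and library sizes. In the gene and interaction tests 100 genes were changed per fold size. Cell filtering, doublet scoring, clustering and class naming were not simulated. For a 2-fold change, edgeR recovered 73% in CD8 T cells (of 11116 genes fitted), 44% in CD4 conventional T cells (8410), 45% in Treg (9067), 70% in NK cells (11828), 69% in macrophages (12840) and 68% in monocytes (13836). For a 4-fold change it recovered 95%, 86%, 90%, 94%, 95% and 94% in the same order. False calls were 15 of 183, 5 of 135, 7 of 142, 5 of 169, 10 of 174 and 15 of 177 calls in that order. For the interactions, 65% of 2-fold and 93% of 4-fold changes were recovered for CD8 T cells against macrophages (10863 genes), and 38% and 90% for CD8 against CD4 conventional T cells (8598 genes). Camera with the preset correlation called all shifted lists in each class and at most 1 of 20 unshifted ones. The genes of these lists were drawn independently, so the rates do not cover lists whose genes move together. Real lists had estimated correlations as high as 0.862 (proliferation in macrophages). With an estimated correlation camera called 85% of shifted lists in NK cells and 0% in the 5 other classes. Fry called 95% of shifted lists in CD8 T cells, 35% in CD4 conventional T cells and 45% in Treg. It called 100% in NK cells, 90% in macrophages and 90% in monocytes, and at most 1 unshifted list per class. Of 4-fold changed shares, 68% were recovered among the 17 classes and 100% among the 18 T and NK clusters, with 3 of 750 and 13 of 800 unchanged shares called.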

Results

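MC38 tumours growing under the skin of 8-week-old mice were profiled by single-cell RNA sequencing of sorted CD45-positive cells, with 2 libraries from WT mice and 2 from mice with a conditional knockout of Trim25 (cKO). Trim25 encodes a ubiquitin ligase, and the series title links its loss in T cells to VISTA, an inhibitory immune checkpoint protein encoded by Vsir. The comparison asks how the immune cells of the tumour differ between the genotypes. After filtering, 39906 cells remained, with a median of 7796, 7864, 8258 and 10017 UMIs per cell in WT-1, WT-2, cKO-1 and cKO-2. The values were deposited UMI counts, summed here per library and cell class.

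Trim25 mRNA was present in every library and was measured lower in both cKO libraries than in both WT libraries over all T cells, without passing the test over all genes. Over all T cells (CD8 T, CD4 conventional T and Treg pooled) it was at 65.1 CPM in WT-1, 61.5 CPM in WT-2, 49.2 CPM in cKO-1 and 44.6 CPM in cKO-2 (log2 fold change -0.42 ± 0.12, adjusted p = 0.26). It was 55.2 ± 2.44 CPM in WT against 41.1 ± 2.80 CPM in cKO CD8 T cells (-0.41 ± 0.13, adjusted p = 0.37). It was 71.6 ± 12.4 against 58.9 ± 3.92 CPM in CD4 conventional T cells (-0.29 ± 0.22, adjusted p = 0.826). In Treg it was 83.7 ± 14.6 against 59.5 ± 0.205 CPM (-0.47 ± 0.20, adjusted p = 0.787). Trim25 was fixed in advance, and its unadjusted p in edgeR was 0.0031 over all T cells. It was 0.0075 in CD8 T cells, 0.21 in CD4 conventional T cells and 0.028 in Treg. Single CD8 T clusters were fitted after the data were seen. Trim25 had -0.52 ± 0.16 in cluster 1, 0.41 ± 0.25 in the Gzmk-high cluster 8 and -0.93 ± 0.28 in cluster 12. The log2 fold change of Trim25 was -0.08 in NK cells, -0.14 in macrophages and -0.05 in monocytes, and 0.06 in monocytes without cKO-1. Over 14 classes it ranged from -0.72 in gamma-delta T cells to 0.23 in B cells. The Trim25 gene lies on chromosome 11 from 88999376 to 89020293 (GRCm38, plus strand). Which exons the allele deletes is not given in the sources used here, and a 3' tag outside the deleted part checks nothing, so these values neither establish nor exclude the knockout.

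Vsir mRNA (chromosome 10 from 60346851 to 60372684, GRCm38, plus strand) passed the test in none of 15 classes in edgeR, with 0 of them under an unadjusted p of 0.05. It was 41.5 ± 9.48 CPM in WT against 41.7 ± 3.82 CPM in cKO CD8 T cells, 75.4 ± 9.38 against 87.1 ± 2.41 CPM in CD4 conventional T cells and 75.8 ± 9.82 against 79.0 ± 3.51 CPM in Treg. Its log2 fold change was 0.05, 0.21 and 0.07 in these classes, 0.10 in NK cells, 0.01 in macrophages, 0.07 in monocytes and 0.06 over all T cells. Leaving out 1 library turned the sign of Vsir in CD8 T cells (-0.17 without WT-2 and -0.07 without cKO-2), Treg (-0.06 without WT-1), NK cells (-0.19 without cKO-1), macrophages (-0.09 without WT-2) and all T cells (-0.05 without WT-2), and brought it to 0 in monocytes (without cKO-1). Protein was not measured.

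**Figure D1:**
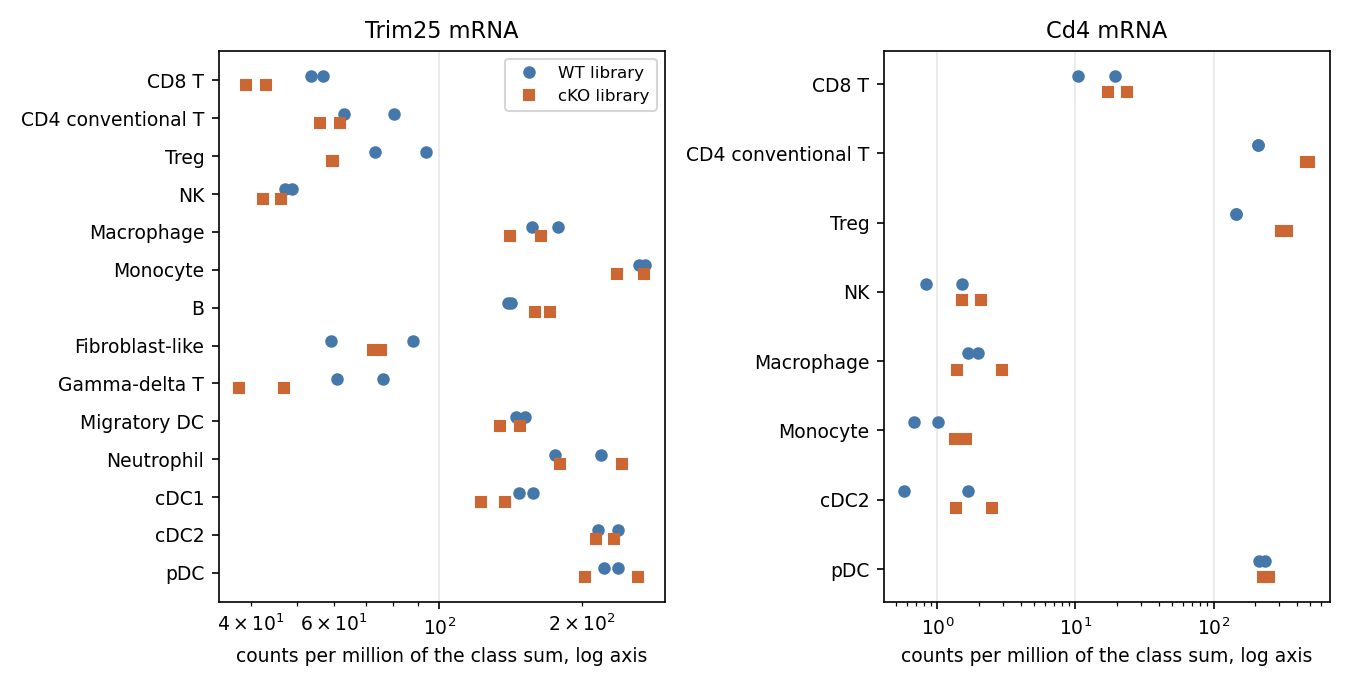
Trim25 (left) and Cd4 (right) mRNA in each cell class where the gene was tested, in CPM of the class sum on a log axis. Each point is 1 library, circles for WT and squares for cKO; Cd4 in CD4 conventional T cells lay at 210.5 and 211.0 in WT and at 470.2 and 495.6 in cKO.

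Monocytes and macrophages made up the largest shares of the cells. Monocytes were 32.3 ± 2.19% of WT and 25.7 ± 3.18% of cKO cells (log2 fold change -0.33, adjusted p = 0.508), and macrophages 14.3 ± 1.53% and 20.3 ± 1.73% (0.51, adjusted p = 0.464). CD8 T cells were 4.64 ± 0.439% and 4.20 ± 0.565% (-0.14, adjusted p = 0.856), CD4 conventional T cells 2.57 ± 0.151% and 1.84 ± 0.392% (-0.48, adjusted p = 0.469), Treg 2.16 ± 0.034% and 1.84 ± 0.147% (-0.23, adjusted p = 0.53), and NK cells 6.49 ± 0.404% and 7.66 ± 0.220% (0.24, adjusted p = 0.53). Gamma-delta T cells, here of a type with Il17a and Il23r among their leading genes, were 0.456 ± 0.174% of WT and 1.20 ± 0.208% of cKO cells (1.39, adjusted p = 0.428). None of 17 class shares passed the edgeR test. That of gamma-delta T cells alone was under an unadjusted p of 0.05, and no other tool was run on shares. Without cKO-1, 2 shares passed, that of gamma-delta T cells among them (1.55), and without cKO-2, 1 passed. With predicted doublets kept the CD8 T share had a log2 fold change of 0.11, and at Leiden resolution 2 the CD4 conventional T share had 0.08. In these settings a Gzmk-led T cell cluster and the larger CD4 conventional T cluster stayed without a class name. The classes therefore held other cells.

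Some cells lay outside the named immune classes. Unnamed cells of low UMI count were 8.10, 3.91, 6.02 and 0.543% of WT-1, WT-2, cKO-1 and cKO-2. Mixed droplets, set apart by a limit chosen after the scores were seen, were 7.29 ± 2.05% of WT and 7.61 ± 1.10% of cKO cells, and T or NK cells without a class name 7.24 ± 0.137% and 7.61 ± 0.145%. A fibroblast-like class, despite the CD45 sort, was 0.675, 1.26, 4.72 and 1.39% of the libraries; Ptprc, which encodes CD45, had a UMI in 53.9% of its cells against 91.8% of B cells, at median depths of 3034 and 3205 UMIs.

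**Figure D2:**
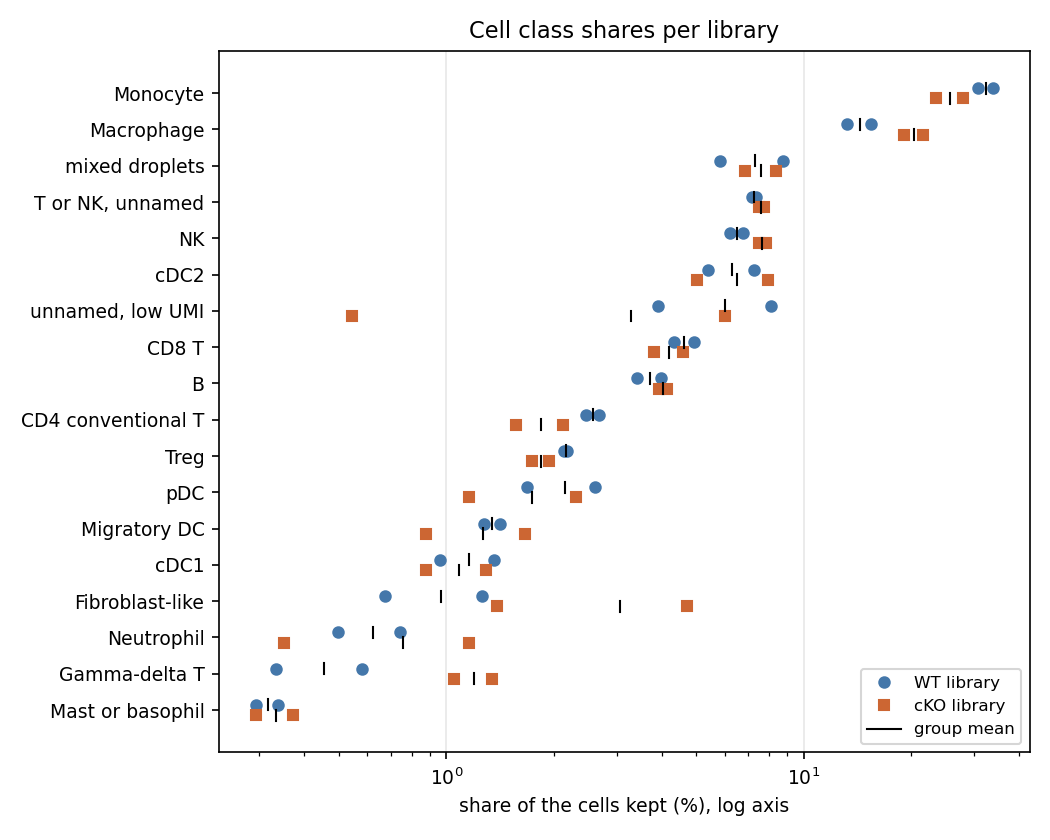
Share of each cell class among the cells kept, in percent on a log axis. Circles are WT and squares cKO libraries, with a bar at the mean of each group; macrophages lay at 15.4 and 13.2% in WT and at 21.6 and 19.1% in cKO.

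Among T and NK cells alone, gamma-delta T cells rose, while a Gzmk-high CD8 T cluster and a cycling cluster without a class name fell. Cluster 10, led by Cd163l1, Trdc, Il23r and Il17a, was 1.89 ± 0.618% of WT and 4.78 ± 0.676% of cKO T and NK cells (log2 fold change 1.33 ± 0.32, adjusted p = 0.00414 in edgeR). Cluster 8, CD8 T cells led by Ccl5 and Gzmk and with the interferon-induced Ifit1bl1 and Ifit3 among its leading genes, was 6.72 ± 0.771% and 3.57 ± 0.970% (-0.92 ± 0.31, adjusted p = 0.0273). Cluster 14, led by the mitotic genes Top2a and Mki67, was 2.54 ± 0.208% and 1.19 ± 0.441% (-1.11 ± 0.36, adjusted p = 0.0273). The direction held in every pair of a WT and a cKO library for the 3 clusters, and the other 15 did not pass. With any 1 library left out no cluster passed. Without WT-1, WT-2, cKO-1 and cKO-2 in turn, cluster 10 had log2 fold changes of 1.04, 1.72, 1.46 and 1.17 (adjusted p = 0.217, 0.431, 0.207 and 0.394). In the same order cluster 8 had -1.03, -0.80, -1.22 and -0.66 (adjusted p = 0.374, 0.442, 0.182 and 0.394) and cluster 14 -1.02, -1.19, -1.52 and -0.75 (adjusted p = 0.416, 0.442, 0.182 and 0.394). Clusters 8 and 14 also lost their calls with TMM factors (adjusted p = 0.0547) and with all cells as denominator (adjusted p = 0.0573).

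In CD4 conventional T cells, the genes that rose include effector and receptor-signalling genes. Cd4 itself rose from 210.8 ± 0.373 to 482.9 ± 17.9 CPM (log2 fold change 1.19 ± 0.15, adjusted p = 0.000403). Il12rb2, a subunit of the interleukin-12 receptor, rose from 36.7 ± 4.54 to 113.9 ± 15.7 CPM (1.64 ± 0.21, adjusted p = 0.000403). Ccl5, a T cell chemokine, rose from 238.2 ± 22.96 to 518.9 ± 46.4 CPM (1.12 ± 0.15, adjusted p = 0.00049), and the chemokine Ccl3 from 20.8 ± 0.828 to 62.7 ± 5.998 CPM (1.59 ± 0.27, adjusted p = 0.00547). Nr4a1, an immediate target of T cell receptor signalling, and Dusp2, a phosphatase of MAP kinases, rose with log2 fold changes of 1.23 ± 0.18 and 1.59 ± 0.21. Over 8668 genes, 14 rose and 7 fell in edgeR.

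The other genes that rose in CD4 conventional T cells include the transporter gene Abcb1b (1.60 ± 0.25), Snx20 (1.10 ± 0.22) and Il1b (0.98 ± 0.20). Il1b is mainly a myeloid transcript, at 1961 ± 65.6 CPM in WT and 3166 ± 174 CPM in cKO monocytes, against 60.7 ± 12.2 and 121.7 ± 11.4 CPM in CD4 conventional T cells. Il17f, an interleukin-17 family cytokine, had a log2 fold change of 3.30 ± 0.67 that rested on 1 library. It was at 12.84, 10.99, 14.97 and 231.4 CPM in WT-1, WT-2, cKO-1 and cKO-2, and its log2 fold change was 0.33 without cKO-2 (adjusted p = 0.964). Markers of gamma-delta T cells in the class were also highest in cKO-2, at 539.5, 567.2, 570.6 and 806.5 CPM in the same order. Of the genes that fell, Rad51b acts in DNA repair (-1.75 ± 0.25, from 116.4 ± 6.23 to 33.6 ± 16.1 CPM), Ncapg2 in chromosome condensation (-1.52 ± 0.32), Fabp5 in fatty acid binding (-1.19 ± 0.19) and Immp2l in the mitochondrion (-0.996 ± 0.205). Dok6, chosen after its values were seen, had 49 counts in WT and 0 in cKO, at least 10.4-fold lower against a floor of 3 counts over the group.

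Of the cytotoxic and effector list, 17 of 18 members measured in CD4 conventional T cells had a log2 fold change above 0 (median 0.55). Over all genes 2 rose (Ccl3 and Ccl5), and 7 rose adjusted over the list alone. Ifng, at 1.20 ± 0.26, and Nkg7, at 0.60 ± 0.16, had adjusted p of 0.0646 and 0.158 over all genes. The list was called by camera (adjusted p = 5.1e-08, and adjusted p = 0.321 with an estimated correlation). Of the proliferation list, 1 of 20 members lay above 0 (median -0.34, adjusted p = 3.59e-06, and adjusted p = 0.321 with an estimated correlation). Over all genes 0 passed, and 2 fell adjusted over the list alone. Stmn1 had -0.82 and Mki67 -0.82. The T cell receptor signalling list was higher with 14 of 17 members above 0 (adjusted p = 0.00146, and adjusted p = 0.321 with an estimated correlation). Over all genes 1 rose (Nr4a1), and 2 rose adjusted over the list alone (Nr4a1 and Tnfrsf9, a costimulatory receptor, 0.85). For Treg function, 12 of 13 members were above 0 (adjusted p = 0.0101, and adjusted p = 0.321 with an estimated correlation), with 4 rising and 1 falling adjusted over the list alone. Among them Areg, a growth factor, had 1.47 and Il1rl1, the interleukin-33 receptor, 1.34. Inhibitory receptors had 11 of 13 above 0 (adjusted p = 0.0181, and adjusted p = 0.436 with an estimated correlation), 3 rising adjusted over the list alone. Pdcd1, which encodes PD-1, had 1.05 and Nr4a2 0.88. Immediate early and stress genes had 13 of 16 above 0 (adjusted p = 0.0118, and adjusted p = 0.648 with an estimated correlation), 1 rising adjusted over the list alone. Junb had 0.52. All 5 measured genes of VISTA and its partners lay above 0 (adjusted p = 0.0118, and adjusted p = 0.321 with an estimated correlation), 1 of them, Pilra, at 1.15, rising adjusted over the list alone. No member of these last 4 lists passed over all genes.

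The other lists did not pass in CD4 conventional T cells: trafficking (adjusted p = 0.0881, with 4 rising and 1 falling adjusted over the list alone), glycolysis and hypoxia (0.0692), interferon gamma and antigen presentation (0.196, with 1 member, Cd74, rising over all genes and 4 adjusted over the list alone, H2-Ab1 at 0.67 among them), type I interferon (0.225), naive and memory genes (0.241), oxidative phosphorylation (0.307) and the unfolded protein response (0.898, with a median of 0.01 and a mean of -0.02). List calls lost with 1 library left out were the inhibitory receptors (adjusted p = 0.582 without WT-2 and 0.281 without cKO-2), receptor signalling (0.0591 without cKO-1), Treg function (0.0507 without cKO-2), stress genes (0.684 with the direction turned without WT-2, 0.0637 without cKO-1 and 0.0806 without cKO-2) and VISTA with partners (0.112 without cKO-1).

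Measured beside these genes, markers of NK cells in the CD4 conventional T class were at 116.3, 120.8, 159.4 and 183.5 CPM in WT-1, WT-2, cKO-1 and cKO-2, and those of macrophages at 1022, 956.9, 1354 and 937.4 CPM. Treg markers were at 1107, 1061, 1288 and 1259 CPM, with Foxp3, Il2ra, Ikzf2, Tnfrsf18 and Ctla4 also in the Treg function list, B cell markers at 47.8, 52.0, 60.8 and 74.8 CPM and CD8 T markers at 69.9, 77.5, 57.2 and 53.8 CPM. Of the 9 NK markers, Gzma, Klrk1 and Eomes are also in the cytotoxic list. At Leiden resolution 2 the class lies mostly in cluster 3, led by Nebl, Rora and Ccr6, and cluster 12, led by Cd4, Slamf6 and Gramd3. Cluster 3 held 62.5 ± 4.18% of the WT and 44.5 ± 6.16% of the cKO cells, and cluster 12 30.8 ± 2.99% and 44.1 ± 7.89%. Fitted alone, Ccl5 had a log2 fold change of -0.002 in cluster 3 and 0.79 in cluster 12, a fit chosen after the values were seen. In these fits the cytotoxic list did not pass in cluster 3 (9 of 16 members above 0, median 0.10, adjusted p = 0.458). It passed in cluster 12 (13 of 17, median 0.37, adjusted p = 0.00599, and adjusted p = 0.292 with an estimated correlation). In cluster 3 proliferation genes were lower (0 of 18 above 0, adjusted p = 3.86e-06), and Treg function (8 of 9, 0.000942) and receptor signalling (15 of 17, 0.002) were higher, each with adjusted p = 0.568 with an estimated correlation. Stress genes were higher there too (0.0288, and adjusted p = 0.804 with an estimated correlation). In cluster 12 receptor signalling (0.0321), trafficking (0.015), glycolysis (0.00872) and the unfolded protein response (0.0321) were higher, each with adjusted p = 0.292 with an estimated correlation. The count of 21 genes became 0 without WT-1 and 0 without WT-2, 60 without cKO-1 and 46 without cKO-2. Without WT-1, Cd4 still had a log2 fold change of 1.17 but an adjusted p of 0.376, and without WT-2 1.21 and 0.35. DESeq2 called 14 genes, but not Abcb1b, Ccl3, Snx20, Il1b, Il17f, Ncapg2 or Immp2l, and at Leiden resolution 2 edgeR called 4. Without cKO-1 the falls of Ncapg2 (adjusted p = 0.211) and Immp2l (0.136), and without cKO-2 the rise of Il1b (0.0607), were not called.

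**Figure D3:**
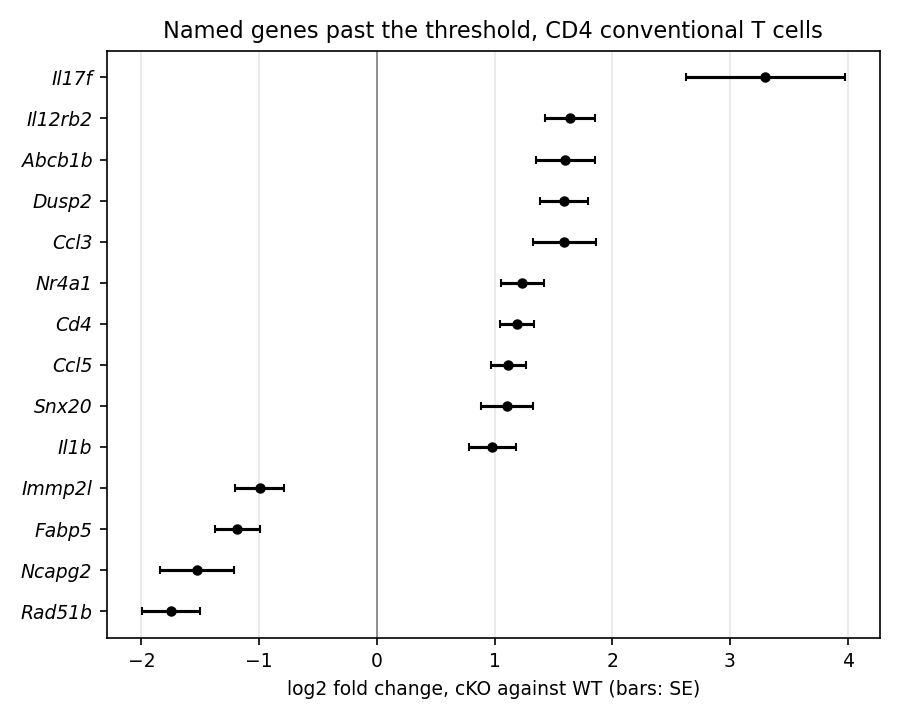
Log2 fold change of cKO against WT, with its standard error as bars, for the named genes past the test in CD4 conventional T cells (2 libraries per genotype). The largest value, that of Il17f, rests on cKO-2.

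In CD8 T cells 1 gene changed: Dusp2 rose from 123.6 ± 11.4 to 223.8 ± 14.4 CPM (log2 fold change 0.88 ± 0.12, adjusted p = 0.0406, 11286 genes tested in edgeR). The granzyme gene Gzmd (-1.76, adjusted p = 0.069), Gzmk (-0.57), Ccl5 (-0.43), Ifng (0.77), the transcription factor gene Irf4 (0.71) and Cd74 (0.62) did not pass. At an unadjusted p under 0.05 there were 839 genes. DESeq2 called 23, and the count was 0 with predicted doublets kept. It was 271 without WT-1, 160 without WT-2, 47 without cKO-1 and 18 without cKO-2.

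Of the stress list in CD8 T cells, 16 of 17 members were above 0 (median 0.25, adjusted p = 0.000838). Its adjusted p was 0.915 with an estimated correlation and 0.632 by fry, which called no list in CD8 T cells. Over all genes 0 members passed, and 4 rose adjusted over the list alone. The chaperone genes Hspa1a and Hsph1 had 0.67 and 0.54. Glycolysis and hypoxia genes had 15 of 19 above 0 (adjusted p = 0.00291, and adjusted p = 0.915 with an estimated correlation), 2 rising adjusted over the list alone, the glucose transporter gene Slc2a1 (0.54) and Bnip3 (0.41). Of the naive, memory and stem-like list, 2 of 15 were above 0 (median -0.27, adjusted p = 0.0121, and adjusted p = 0.915 with an estimated correlation), 2 falling adjusted over the list alone, the receptor gene Slamf6 (-0.68) and the transcription factor gene Lef1 (-0.78). No member of the last 2 lists passed over all genes. Calls were lost for stress without WT-2 (adjusted p = 0.666), for glycolysis without WT-2 (0.46) and cKO-2 (0.557), and for naive genes without WT-1 (0.0952) and cKO-2 (0.557). The cytotoxic list (adjusted p = 0.91) had a median of 0.10 but a mean of -0.08 and a test direction of down, with 3 rising and 4 falling adjusted over the list alone. The inhibitory receptors (0.889) had a median of 0.13 and a mean of -0.04, trafficking 0.03 and -0.05, interferon gamma -0.05 and 0.02, and VISTA with partners 0.05 and -0.02. Receptor signalling (0.353), Treg function (0.889), trafficking (0.889), type I interferon (0.556), interferon gamma (0.889), proliferation (0.556), oxidative phosphorylation (0.28), the unfolded protein response (0.328) and VISTA with partners (0.889) did not pass. Cluster 1, led by Cd8a, Pdcd1 and Cxcr6, held 52.6 ± 4.35% of WT and 64.7 ± 6.33% of cKO CD8 T cells, and the Gzmk-high cluster 8 held 34.7 ± 2.70% and 21.6 ± 7.97%. In fits of single clusters, chosen after the values were seen, stress genes were higher in cluster 1 (16 of 17 above 0, adjusted p = 0.000145, and adjusted p = 0.979 with an estimated correlation). They did not pass in cluster 8 (6 of 17, 0.993). Naive genes did not pass in cluster 1 (4 of 14, 0.195) or cluster 8 (7 of 12, median 0.17, 0.336). Proliferation genes were lower in cluster 1 (0.0131, and adjusted p = 0.979 with an estimated correlation). In cluster 8 glycolysis (16 of 16, 0.00366) and type I interferon (21 of 28, 0.0426) were higher, each with adjusted p = 0.714 with an estimated correlation. Glycolysis did not pass in cluster 1 (14 of 19, 0.0553) or cluster 12 (11 of 19, 0.427). In cluster 12 naive genes were lower (0.0289), and type I interferon (22 of 27, 0.00185), interferon gamma (18 of 25, 0.00589), stress (0.0168), inhibitory receptors (0.0289), VISTA with partners (0.0415), receptor signalling (0.0451) and Treg function (0.0455) were higher. All of these in cluster 12 had adjusted p = 0.416 with an estimated correlation. As single genes, 9, 14 and 3 passed in clusters 1, 8 and 12 in edgeR. Macrophage markers in the class were at 815.7, 704.1, 1014 and 1017 CPM in WT-1, WT-2, cKO-1 and cKO-2.

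In Treg, Cd4 and Ptms rose and the granzyme gene Gzmb and Penk, which encodes the opioid precursor proenkephalin, fell. Cd4 rose from 145.0 ± 0.644 to 324.7 ± 20.3 CPM (log2 fold change 1.18 ± 0.15, adjusted p = 0.000179). Ptms, which encodes parathymosin, rose from 51.0 ± 13.01 to 114.4 ± 6.76 CPM (1.16 ± 0.20, adjusted p = 0.0115). Gzmb fell from 3694 ± 123 to 2269 ± 399 CPM (-0.69 ± 0.14, adjusted p = 0.0277) and Penk from 136.8 ± 56.9 to 53.9 ± 6.78 CPM (-1.33 ± 0.23, adjusted p = 0.0115). Over 9322 genes, 6 rose and 4 fell in edgeR, with 539 at an unadjusted p under 0.05, and DESeq2 called 2, Cd4 and Gzmb. Mmp12, a macrophage elastase gene, rose by 2.33 ± 0.41; it was at 16.7, 8.91, 101.5 and 27.6 CPM in the Treg of WT-1, WT-2, cKO-1 and cKO-2 and at 36.8, 17.7, 177.7 and 32.4 CPM in their monocytes.

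Bank1 (-3.22), Ccl1 (-2.17) and Cd8a (1.96, from 6.62 ± 0.263 to 25.9 ± 1.00 CPM) also passed in Treg, under the 20 CPM minimum, and were chosen after their values were seen. Bank1 is a B cell gene, and B cell markers were at 283.9, 232.1, 224.7 and 273.8 CPM in the Treg of WT-1, WT-2, cKO-1 and cKO-2; macrophage markers were at 909.1, 1041, 1506 and 1204 CPM. NK markers, Gzma among them, were at 132.6, 115.3, 47.5 and 91.1 CPM. No list passed in Treg. The smallest adjusted p was that of naive and memory genes (0.0686; adjusted p = 0.973 with an estimated correlation), with 3 of 12 members above 0 and 2 falling adjusted over the list alone, the transcription factor gene Bach2 (-0.92) among them. The others were glycolysis and hypoxia (0.148), oxidative phosphorylation (0.188), cytotoxic molecules (0.901, with 4 falling adjusted over the list alone, Gzma at -1.21), receptor signalling (0.901), interferon gamma (0.901), proliferation (0.901), stress genes (0.901, with Hspa1b at -0.97), VISTA with partners (0.901), inhibitory receptors (0.914, with Pdcd1 at 0.63 and Nrn1 at -1.23), Treg function (0.914), trafficking (0.914), type I interferon (0.914) and the unfolded protein response (0.914). Median and mean differed in sign for trafficking (0.04 and -0.03), type I interferon (0.02 and -0.01) and stress genes (0.07 and -0.00). The count of 10 genes was 15 without WT-1 (4 higher and 11 lower), 15 without WT-2 (7 and 8), 11 without cKO-1 (5 and 6) and 2 without cKO-2 (2 and 0). Cd4 kept its call in each. Ptms lost its call without WT-1 (adjusted p = 0.0927), cKO-1 (0.069) and cKO-2 (0.133), Penk without WT-2 (0.248), cKO-1 (0.0917) and cKO-2 (0.144), Gzmb without cKO-1 (0.651) and cKO-2 (0.144). Mmp12 lost its call without cKO-1 (0.651), where it was 1.14. Bank1 lost its call without WT-1 (0.609) and cKO-2 (0.205), Ccl1 without WT-2 (0.304) and cKO-2 (0.394), and Cd8a without each of the libraries (0.0927, 0.0705, 0.0918 and 0.144).

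In NK cells no gene passed in edgeR over 12008 tested, with 686 at an unadjusted p under 0.05 and 15 called by DESeq2. Glycolysis and hypoxia genes were higher as a list, with 18 of 19 members above 0 (median 0.23, adjusted p = 5.92e-06, and adjusted p = 0.883 with an estimated correlation) and 3 rising adjusted over the list alone. Among them the vascular growth factor gene Vegfa was at 50.6 ± 11.5 CPM in WT and 78.9 ± 8.96 CPM in cKO (0.69) and the pyruvate kinase gene Pkm had 0.37. Fry gave this list an adjusted p of 0.818 and called no list in NK cells. Stress genes had 15 of 17 above 0 (adjusted p = 0.00153, and adjusted p = 0.883 with an estimated correlation), 1 rising adjusted over the list alone, Jund at 0.46. Naive and memory genes had 12 of 14 above 0 (adjusted p = 0.0295, and adjusted p = 0.883 with an estimated correlation), none past the test in either adjustment, with Il7r at -0.79 and Satb1 at 0.50. The chemokine gene Ccl4 (0.44), Ifng (0.57) and Nr4a1 (0.59) were measured higher and the granzyme gene Gzmf (-0.9995) and the interferon-inducible Iigp1 (-0.65) lower, none past the test over all genes. The lists that did not pass were receptor signalling (adjusted p = 0.113), VISTA with partners (0.686, median 0.10, mean -0.02) and, each at 0.609, cytotoxic molecules (median 0.06, mean -0.02), inhibitory receptors (median -0.04, mean 0.01), Treg function, trafficking, type I interferon, interferon gamma, proliferation, oxidative phosphorylation and the unfolded protein response. The gene count was 443 without WT-1, 55 without WT-2, 38 without cKO-1 and 66 without cKO-2, and calls were lost for naive genes without WT-2 (0.89) and cKO-1 (0.699) and for stress without WT-2 (0.89) and cKO-2 (0.0687).

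In macrophages no gene passed in edgeR over 13072 tested, with 704 at an unadjusted p under 0.05 and 22 called by DESeq2. Glycolysis and hypoxia genes were higher as a list, with 16 of 19 members above 0 (median 0.25, adjusted p = 5.21e-05, and adjusted p = 0.862 with an estimated correlation) and 6 rising adjusted over the list alone. Fry gave this list an adjusted p of 0.593 and called no list in macrophages. Vegfa had 0.90 and Pkm 0.42. All 22 proliferation genes lay above 0 (median 0.23, adjusted p = 0.000297, and adjusted p = 0.862 with an estimated correlation), none past the test in either adjustment. Mki67 was at 43.9, 74.4, 89.4 and 95.7 CPM in WT-1, WT-2, cKO-1 and cKO-2, and Top2a had a log2 fold change of 0.61. The cycling cluster 25 was 2.07 ± 1.31% of WT and 4.20 ± 0.593% of cKO macrophages, and without WT-1 the direction of the proliferation list turned (adjusted p = 0.963). Of the inflammatory list 10 of 15 were above 0 (adjusted p = 0.00728, and adjusted p = 0.862 with an estimated correlation), 6 rising and 1 falling adjusted over the list alone. These include the interleukin-1 genes Il1b (2215 ± 153 to 3227 ± 15.1 CPM, 0.54) and Il1a (0.48), the costimulatory ligand gene Cd80 (0.57) and the chemokine gene Ccl5 (-0.56). The call was lost without WT-2 (0.67) and cKO-2 (0.0845).

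The other lists did not pass in macrophages: lipid and phagocytic genes (adjusted p = 0.0812, with Fabp4, a fatty acid binding protein gene, at -1.21), type I interferon (0.0916), chemoattractants (0.163, with Cxcl2 at 0.84), the unfolded protein response (0.223), stress (0.356), oxidative phosphorylation (0.419), interferon gamma (0.648), tissue-repair genes (0.648, with Spp1, which encodes osteopontin, at -0.72), VISTA with partners (0.764) and other checkpoint ligands (0.784). T cell markers in the class were at 24.1, 41.5, 26.6 and 30.1 CPM in WT-1, WT-2, cKO-1 and cKO-2, neutrophil markers at 194.4, 153.2, 244.3 and 216.0 CPM and markers of conventional type 2 dendritic cells at 297.2, 333.1, 380.7 and 366.4 CPM. The gene count was 18 without WT-1, 18 without WT-2, 1 without cKO-1 and 0 without cKO-2.

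Monocytes showed higher glycolysis and hypoxia genes in cKO as a list in camera with the preset correlation. All but 1 single gene fell short of the test. All 19 glycolysis and hypoxia members lay above 0 (median 0.36, adjusted p = 2.42e-09, and adjusted p = 0.578 with an estimated correlation), 12 rising adjusted over the list alone. Fry gave this list an adjusted p of 0.332 and called no list in monocytes. The enzyme genes Tpi1, Pkm and Gapdh had 0.58, 0.45 and 0.48. Chemoattractants had 11 of 13 above 0 (adjusted p = 0.000251, and adjusted p = 0.644 with an estimated correlation), 6 rising adjusted over the list alone. The neutrophil chemokine genes Cxcl1 and Cxcl2 had 2.51 and 1.19 (Cxcl2 from 179.6 ± 65.7 to 404.0 ± 67.5 CPM). The 1 gene past the test over 14092 genes in edgeR was the metallothionein gene Mt2, chosen after its value was seen because it lay under 20 CPM; it rose from 4.49 ± 0.041 to 14.0 ± 0.590 CPM (1.67 ± 0.15, adjusted p = 0.0269).

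Tissue-repair and suppressive genes had 13 of 16 above 0 in monocytes (adjusted p = 0.00121, and adjusted p = 0.578 with an estimated correlation), 7 rising adjusted over the list alone, with the arginase gene Arg1 at 0.79. Inflammatory genes had 10 of 16 above 0 (adjusted p = 0.00411, and adjusted p = 0.644 with an estimated correlation), 5 rising adjusted over the list alone. Ptgs2, which encodes cyclooxygenase 2, was at 287.1 ± 65.5 CPM in WT and 576.2 ± 45.3 CPM in cKO (1.03), Il1b had 0.71 and Il1a 1.20. Other checkpoint ligands had 9 of 11 above 0 (adjusted p = 0.00411, and adjusted p = 0.578 with an estimated correlation), 2 rising adjusted over the list alone, Pvr (0.61) and Cd80 (0.69). No member of the 5 lists called in monocytes passed over all genes. Lists that did not pass were stress (adjusted p = 0.0556), proliferation (0.0586), the unfolded protein response (0.0586), lipid and phagocytic genes (0.0853, with 2 rising and 2 falling adjusted over the list alone, Fabp4 at -1.14), type I interferon (0.15), VISTA with partners (0.306), interferon gamma (0.766) and oxidative phosphorylation (0.766). Calls were lost for inflammatory genes without WT-2 (0.246) and cKO-2 (0.507), tissue repair without cKO-1 (0.0952) and chemoattractants without WT-2 (0.0575) and cKO-2 (0.106). Cluster 10, led by Thbs1, Cd14, Vegfa and Ptgs2, held 9.46 ± 1.88% of WT and 22.02 ± 5.94% of cKO monocytes, and cluster 4 28.6 ± 0.955% and 22.1 ± 0.103%. Macrophage markers, of which Mrc1 and Trem2 are also in the tissue-repair list, were at 1603, 1751, 1952 and 1814 CPM in the monocytes of WT-1, WT-2, cKO-1 and cKO-2. DESeq2 called 63 genes; the edgeR count was 214 without WT-1, 1 without WT-2, 3 without cKO-1 and 32 without cKO-2.

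**Figure D4:**
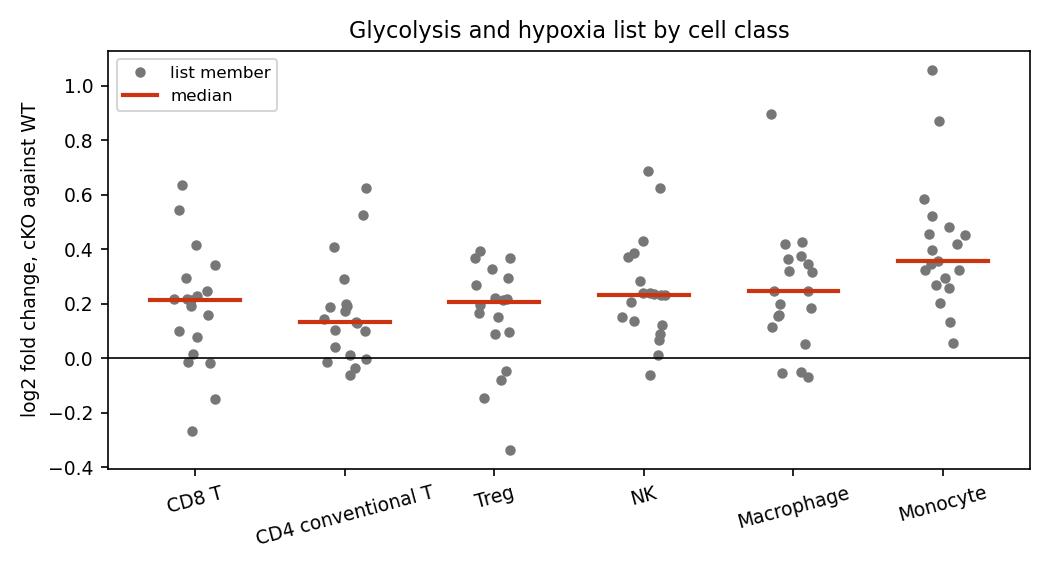
Log2 fold change of cKO against WT for each measured member of the glycolysis and hypoxia list in the 6 main classes, with a line at the median. All 19 members lay above 0 in monocytes and 18 of 19 in NK cells.

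Among the 9 other classes 79 genes passed in edgeR, 23 of them in B cells, 55 in plasmacytoid dendritic cells and 1 in conventional type 2 dendritic cells. In B cells 22 of the 23 fell, and in plasmacytoid dendritic cells 49 of 55. Those named here were chosen after their values were seen. In plasmacytoid dendritic cells they were Adgre1 (-3.31 ± 0.33), Chil3 (-3.10 ± 0.33), Lyz2 (-2.05 ± 0.25, from 355.0 ± 96.4 to 80.2 ± 38.5 CPM) and Csf1r. In that class the macrophage markers were at 561, 992.4, 410.0 and 354.7 CPM in WT-1, WT-2, cKO-1 and cKO-2, and the monocyte markers at 7464, 7505, 6900 and 7382 CPM. In B cells they were the monocyte genes Ly6c2 (-1.50 ± 0.15, from 350.1 ± 12.8 to 124.3 ± 12.6 CPM) and Lyz2 (-0.85 ± 0.14) and the plasma cell genes Jchain (-2.09 ± 0.32) and Xbp1 (-1.45 ± 0.27). Plasma cell markers in the B cell class were at 6677, 17505, 3288 and 3162 CPM in WT-1, WT-2, cKO-1 and cKO-2, and monocyte markers at 1848, 1968, 1058 and 1356 CPM. The total over the 9 classes was between 380 and 849 with 1 library left out. Without WT-1, WT-2, cKO-1 and cKO-2 in turn, B cells had 206 (69 higher and 137 lower), 143, 102 and 104 genes. Plasmacytoid dendritic cells had 144, 165, 42 and 185 genes and conventional type 2 dendritic cells 122, 12, 52 and 94. DESeq2 called 27, 39 and 19 genes in these 3 classes.

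The genotype effect was compared between CD8 T cells and macrophages, since the series title places the deletion in T cells. Over 13294 genes, 7 differed in edgeR (5 with a larger log2 fold change in CD8 T cells), with 858 at an unadjusted p under 0.05 and 11 by DESeq2. Without WT-2 there were 73, 18 of them with a larger and 55 with a smaller log2 fold change in CD8 T cells. Hspa1a differed by 1.19 and Hspa1b by 0.86, both heat-shock genes, while Ifitm1 differed by -1.13. Hspa1b lost this call without cKO-1 (adjusted p = 0.121). Between CD8 and CD4 conventional T cells 65 of 11012 genes differed, 38 of them with a smaller log2 fold change in CD8 T cells. Ccl5 rose in CD4 conventional T cells and was measured lower in cKO CD8 T cells, a difference of -1.53 ± 0.11 (adjusted p = 4.65e-15), Il12rb2 differed by -1.39 ± 0.21 and Rad51b by 1.74 ± 0.23. At an unadjusted p under 0.05 there were 813 genes. DESeq2 called 5, and without cKO-1 the edgeR count was 113.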

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

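Of the tests in this part, those of NK cells, of CD8 T cells and of the genes called again within cluster 3 were chosen after the result was seen.

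Results are listed here because the effect of the genotype differed between cell classes in a test of that difference itself. For CD8 T cells against macrophages 7 genes differed, given as the log2 fold change in CD8 T cells minus that in macrophages. These were the heat-shock genes Hspa1a (1.19) and Hspa1b (0.86), Rgs2 (0.86), Ern1 (0.97), Itgav (0.67), Ifitm1 (-1.13) and Trerf1 (-0.92). Hspa1b was lost without cKO-1 (adjusted p = 0.121), Ern1 without WT-1 (0.0808) and cKO-1 (0.136), Trerf1 without WT-1 (0.0606), cKO-1 (0.136) and cKO-2 (0.25), and Itgav without WT-1 (0.106), cKO-1 (0.0611) and cKO-2 (0.25).

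Between CD8 and CD4 conventional T cells 65 genes differed. The named ones were Ccl5 (-1.53), Rad51b (1.74), Tnfsf8 (-1.19), Il12rb2 (-1.39), Ly6c2 (-0.88), Gramd3 (-0.91), Itgb1 (-0.80), Tmem176b (1.14), Il1rl1 (-2.54) and Gimap6 (-0.69), each the log2 fold change in CD8 T cells minus that in CD4 conventional T cells. Itgb1 was lost without cKO-2 (adjusted p = 0.1), Il1rl1 without WT-1 (0.273) and Gimap6 without WT-2 (0.15). DESeq2 did not call Gramd3 (adjusted p = 0.0559), Itgb1 (0.312), Tmem176b (0.534), Il1rl1 (0.9999) or Gimap6 (0.534).

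The effector genes higher in cKO CD4 conventional T cells, Ccl5 among them, were weighed against NK cells, CD8 T cells and another mix of clusters in the class. Other sources of Ccl5 were not weighed. Among these are migratory dendritic cells, with Ccl5 at 7645 ± 2601 CPM in WT and 7100 ± 115 CPM in cKO. The T or NK cluster 6 without a class name, with Ly6c2, Ccl5 and Gramd3 among its leading genes, is another. NK cells that brought the rise of Ccl5 would have raised Gzma and Gzmb with it, but their rise was 0.0498 of the amount needed, and for CD8 T cells the rise of Cd8a and Cd8b1 was -0.0669 of it, so the tables argue against both as the source of Ccl5. Another mix of clusters cannot be told apart for the called genes other than Cd4 as a set, of which 19 were tested in cluster 3 and Il12rb2 was not: within cluster 3 alone their median log2 fold change in the direction of the call was 0.76, against 1.19 in the class, but their SD of 1.65 is above both and the comparison decides nothing. In that cluster 5 of the 19 passed on their own, Ccl3, Nr4a1 and Il17f higher and Rad51b and Dok6 lower. Il17f rests on cKO-2. For the others of these 5 this argues against the mix of clusters 3 and 12 as the whole cause. The cells are part of those that gave the calls, so this is no separate support for the changes. Ccl5 had -0.002 in cluster 3 and 0.79 (adjusted p = 0.093) in cluster 12, so the mix stays open for it. An effect of Trim25 loss in these cells is an open hypothesis that the tables do not tell from it.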

How the results depend on the processing

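Leiden resolution 2 for T and NK clusters, a crossed pairing and the fits of single clusters were chosen after seeing the data. With a library left out, the lone library of its genotype is assumed to vary like the others.

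Directions turned for the CD8 T share with doublets kept (0.11) and the CD4 conventional T share at Leiden resolution 2 (0.082). With each library left out in turn, the adjusted p of the stress list in CD4 conventional T cells ran from 1.11e-06 to 0.684 (turned without WT-2) and that of the proliferation list in macrophages from 1.11e-11 to 0.963 (turned without WT-1). Vsir in CD8 T cells ran from -0.17 to 0.28 and was below 0 without WT-2 and without cKO-2 (-0.07), Vsir in Treg cells from -0.059 (without WT-1) to 0.23, Vsir in NK cells from -0.19 (without cKO-1) to 0.36 and Vsir in Macrophage cells from -0.089 (without WT-2) to 0.12. Vsir in All T cells ran from -0.049 (without WT-2) to 0.16, Vsir in Monocyte cells from 0 (without cKO-1) to 0.12 and Trim25 in Monocyte cells from -0.19 to 0.057 (without cKO-1). The cause of the turns with a library left out was not tested.

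Counts moved by over 1.5 times as follows, and the cause was not tested. DESeq2 called 23 genes in CD8 T cells, 2 in Treg, 15 in NK cells, 22 in macrophages and 63 in monocytes, and 11 and 5 for the differences of CD8 T cells from macrophages and from CD4 conventional T cells. With no filter on low counts the numbers were 188 in CD8 T, 80 in CD4 conventional T, 29 in Treg, 136 in NK, 213 in monocytes, 986 in the other classes, 102 for CD8 T cells against macrophages and 62 named genes. At Leiden resolution 2 they were 4 in CD8 T, 4 in CD4 conventional T, 1 in NK, 0 in monocytes and 7 T and NK clusters. With thinned sums they were 13 in CD8 T, 13 in CD4 conventional T and 1 in Treg, and in CD8 T 15 with stricter cells and 0 with doublets kept. TMM factors and all cells as denominator each left 1 T and NK cluster. An estimated correlation and fry left 0 and 0 of 21 lists.

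The replicate block gave 59 genes in CD8 T, 73 in CD4 conventional T, 3 in NK and 70 in monocytes. It gave 416 in the other classes, 1 T and NK cluster and 47 named genes. For the differences of CD8 T cells it gave 0 and 2, and it lost 15 of the 17 interaction genes. In these differences the block took the place of the library term, so the 2 class sums of a library were no longer paired. The loss of the interaction genes therefore cannot be read as an effect of the replicate number. The labels share numbers but do not pair the libraries, and there are 2 pairs. At Leiden resolution 2 over all cells, the unnamed cluster 35 held 259, 0, 40 and 0 cells of WT-1, WT-2, cKO-1 and cKO-2. A batch shared by equal numbers is therefore not excluded. The correlation of replicate differences between genotypes was from -0.102 in monocytes to 0.0862 in Treg, and a crossed pairing called 29 genes in monocytes.

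With each library left out in turn, the counts ran from 18 to 271 in CD8 T, 0 to 60 in CD4 conventional T, 2 to 15 in Treg, 38 to 443 in NK, 0 to 18 in macrophages, 1 to 214 in monocytes and 380 to 849 in the other classes. They ran from 5 to 73 and 45 to 113 for the differences of CD8 T cells, 0 to 2 class shares, 0 to 0 T and NK clusters, 17 to 26 lists and 21 to 38 named genes. Of 778 comparisons of named genes 562 kept direction and side of the threshold, 64 lost and 144 gained a call. Of 189 list comparisons 118 kept and 69 lost it, of 136 for interaction genes 104 and 32, and of 91 for shares 70 and 18.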

Other observations

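The tests of Cd4 against plasmacytoid dendritic cells and of mt-Nd2 in the fibroblast-like class, the single-cluster fits and the genes followed across classes were chosen after the result was seen.

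Within single clusters, the glycolysis and hypoxia list was higher in cKO in monocyte cluster 1 (19 of 19 members above 0, adjusted p = 0.00011, and adjusted p = 0.488 with an estimated correlation) and cluster 2 (18 of 19, adjusted p = 0.00565, and adjusted p = 0.956 with an estimated correlation). It did not pass in cluster 4 (0.0805) or in the Thbs1-high and Vegfa-high cluster 10 (0.228). In macrophages it was higher in cluster 0 (adjusted p = 6.81e-05, and adjusted p = 0.5 with an estimated correlation) and in cluster 5 (4.51e-06, and adjusted p = 0.741 with an estimated correlation). Cluster 5 has a median of 2214 UMIs per cell against 13390 in cluster 0. Proliferation genes did not pass in macrophage cluster 0 (0.484) or 5 (0.15), outside the cycling cluster 25. Inflammatory genes (0.00376) and chemoattractants (0.0391) were higher in macrophage cluster 0, each with adjusted p = 0.812 with an estimated correlation, and did not pass in cluster 5 (0.184 and 0.359). In cluster 5 lipid and phagocytic genes were lower (0.0241, and adjusted p = 0.741 with an estimated correlation) and type I interferon genes higher (0.0482, and adjusted p = 0.897 with an estimated correlation). Neither list passed in cluster 0, with 9 of 17 lipid and phagocytic (0.445) and 5 of 28 type I interferon genes (0.187) above 0. Chemoattractants (6.9e-05), inflammatory genes (0.00011), tissue-repair genes (0.00577) and checkpoint ligands (0.0136) were higher and proliferation genes lower (0.00278) in monocyte cluster 1, each with adjusted p = 0.488 with an estimated correlation. Chemoattractants did not pass in monocyte cluster 2 (0.576) or 4 (0.127), nor did inflammatory genes (0.492 and 0.0577). In clusters 2, 4 and 10 tissue-repair genes (0.775, 0.0577 and 0.513) and checkpoint ligands (0.09, 0.117 and 0.0764) did not pass. Stress genes were higher in cluster 1 (0.0203, and adjusted p = 0.861 with an estimated correlation) and did not pass in clusters 2, 4 and 10 (0.728, 0.702 and 0.228). In cluster 10 chemoattractants (0.0351), inflammatory genes (0.023) and also proliferation genes (0.0351) were higher, each with adjusted p = 0.766 with an estimated correlation. In cluster 2 proliferation genes were lower (0.0266, and adjusted p = 0.956 with an estimated correlation). As single genes, 0 passed in edgeR in each of monocyte clusters 1, 2, 4 and 10, with 536, 460, 730 and 350 at an unadjusted p under 0.05; DESeq2 was not run there. In macrophages 0 passed in cluster 0 and 16 in cluster 5, 10 of them higher in cKO.

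Some genes moved across many of 15 classes. Dusp2, a phosphatase of MAP kinases, was higher in 12 classes and passed in 3 (CD8 T, CD4 conventional T and B cells), from -0.67 in mast cells or basophils to 1.59 in CD4 conventional T cells. Ptms, which lies within 500000 bp of Cd4, was higher in all 15 and passed in 1 (Treg, 1.16). Of the 27 genes tested in that window in Treg, Tapbpl was highest with 1.19 and did not pass (adjusted p = 0.163), and the median was 0.035. In CD4 conventional T cells the highest of 24 was Ptms with 0.51, and the median was 0.17. Ccl5 was higher in 2 of 15, with 1.12 in CD4 conventional T cells, and lowest in mast cells or basophils (-2.74). Over all T cells pooled, Dusp2 (0.98 ± 0.11, adjusted p = 0.00526), Cd4 (0.95), Ptms (0.92) and the unnamed gene model Gm43305 rose, 4 of 12091 genes. That count was 112, 36, 181 and 74 without WT-1, WT-2, cKO-1 and cKO-2 in turn, 27 by DESeq2 and 1 with DESeq2 size factors.

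Cd4 rose in CD4 conventional T cells (1.19) and Treg (1.18), and in Treg its neighbour Ptms rose too. The log2 fold change of Cd4 was above 0 in all 8 classes tested, with no overlap between the genotypes in 4. In CD8 T cells fitted by cluster in edgeR, Cd4 passed in cluster 8 (1.93 ± 0.31, adjusted p = 0.012) and had -0.25 in cluster 1. A difference between the libraries that acts alike on Cd4 in every cell type is argued against by plasmacytoid dendritic cells. They express Cd4 at 224.4 ± 15.1 CPM in WT, and its log2 fold change was larger in CD4 conventional T cells by 1.07 ± 0.17. With values above 0 in all 8 classes, a smaller rise in every cell type is not excluded. Monocytes had 0.82 ± 0.35, at 0.84 CPM in WT and 1.48 CPM in cKO. A larger part of true CD4 T cells in the cKO class is argued against by Cd40lg and Izumo1r, whose mean log2 fold change was 0.40 ± 0.18 against 1.19 for Cd4. This rests mainly on Cd40lg (0.03 ± 0.15), since Izumo1r had 0.78 ± 0.32. At Leiden resolution 2 the Cd4-led cluster 12 held more of the cKO class. Fitted alone, Cd4 had 1.26 in cluster 12 and 1.26 in cluster 3. Tags from a Cre transgene that carries Cd4 sequence stay a possible explanation: Treg differed from plasmacytoid dendritic cells by 1.05 ± 0.17, but the Cre driver is not given in the sources used here and the reads were not used here. An effect of Trim25 loss on Cd4 stays open beside it, untested.

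The mitochondrial gene mt-Nd2 (chromosome M from 3914 to 4951, GRCm38) was higher in cKO in all 15 classes tested with no overlap between the genotypes, from 0.36 in CD4 conventional T cells to 0.71 in B cells, and passed in 1 of them. More mitochondrial RNA in the cKO libraries is argued against by the other 12 mitochondrial protein-coding genes in monocytes, with a median log2 fold change of 0.12 and an SD of 0.14 against 0.55 for mt-Nd2. The highest of these 12 was mt-Atp8 with 0.47 ± 0.15, near mt-Nd2, and the lowest mt-Nd5 with -0.06 ± 0.16. A mitochondrial sequence variant of the cKO mice may account for the rise of mt-Nd2 but cannot be told apart here. The fibroblast-like class showed 0.53 ± 0.12, and whether its cells come from the host or from the injected line is open. Tm4sf1 was in 43.4% and Rhox5 in 74.1% of them, against at most 2.30 and 7.67% in any other class, but Krt8 and Krt7 were each in 0.136%, Epcam in 0.271%, Krt18, Krt20, Cldn4 and Krt19 in 0%, and Col1a1 in 26.4%.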
